A study of Danio rerio with 5 samples.

How the data were processed

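RNA from the upper digestive tract of adult zebrafish was measured on 5 arrays of Affymetrix type, 1 array per pool of 3 fish aged 3 months. There were 3 pools of zCdx1b transgenic fish and 2 pools of wild-type fish, which the labels call biological replicates. Per the labels' protocols, total RNA was extracted with TRIzol and amplified into biotin-labelled cRNA by in vitro transcription.

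The values analysed were the log2 expression values the authors deposited, with 1 value per probe set and array. MAS5 is named in the submitters' processing notes. Its version, its scaling target and the step that put the values on a log scale are not given in the sources used here. The log2 scale was taken from the values themselves, which ran from 2.23 to 13.58 on the transgenic arrays and from 2.24 to 13.26 on the wild-type arrays. Each array had a mean of 4.89 over all probe sets, so the deposited values had been scaled array by array. Their standard deviation still differed, from 1.58 on wild-type pool 2 to 1.79 on wild-type pool 1. If the base were not 2, the folds given would change, whereas the directions and the tests would not. No detection calls and no scanner intensities were used here, and no genome was used, so no coordinates are given.

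The table held 15502 probe sets besides 115 control probe sets, which were left out of the tests of genes. Gene names came from GEO's platform annotation, with symbols updated through Entrez identifiers against a RefSeq gene table of the zebrafish assembly GRCz12tu. Of the 15502 probe sets, 10795 had 1 symbol, 135 had several and 4572 had none, and no gene was named from a probe set with several. No probe set bore the name cdx1b in these tables.

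Probe sets were kept when they reached the 40th percentile of their array on at least 2 of the 5 arrays, which left 10335 and removed 5167. Transgenic and wild-type pools were compared with limma, using lmFit and eBayes with a mean-variance trend and no covariate. The tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. No further normalization was applied. Errors of log2 changes are standard errors from that model, and the number of arrays limits the precision.

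A total of 22 gene lists had been fixed before the data were examined, with older symbols matched through synonyms. They covered intestinal absorptive, goblet and mucus secretory, enteroendocrine, squamous epithelium, exocrine pancreas, hepatocyte, smooth muscle, striated muscle, leukocyte, erythrocyte and gonad markers. The others were cdx and hox genes, fibroblast and extracellular matrix genes, inflammatory and acute phase genes, interferon response genes, cell cycle genes, hedgehog, wnt, bmp and notch pathway genes, cholesterol synthesis genes, immediate early and stress genes, circadian clock genes, ribosomal protein genes and oxidative phosphorylation genes. A gene was represented by its probe set with the highest mean level, which gave 6479 genes. Lists with at least 5 measured genes were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists. camera was repeated with the correlation estimated from the residuals, and fry, which tests a list against no change where camera tests it against other genes, was run beside it. A list's rises and falls were counted over all probe sets and again adjusted over the list alone.

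Genes were named by a rule set before the data were examined. It took every cdx1b, cdx1a and cdx4 probe set, and the 12 genes with the largest rise and the 12 with the largest fall past the threshold without overlap between the groups. It also took up to 4 members of each list with the largest change past the threshold. Other genes are said to have been chosen after their values were seen. No named gene had probe sets past the threshold in opposite directions.

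A background bound was chosen after the data were seen. It was the highest value, on each array, of 44 control probe sets for bacterial and tag sequences. It lay between 3.64 and 4.13 and was highest on wild-type pool 2. That array had the fewest probe sets above its bound, 62.4% against 65.2% to 72.0% on the others. The spike-in control bioB, not among these 44, also read highest there, at 7.45 against 5.61 to 6.75. Where all arrays of the dimmer group were at or below the bound, the fold is written as at least N-fold. That fold sets the brighter group's mean against the dimmer group's mean of the bound, or of the probe set's own value where higher.

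The alternatives fixed before the data were examined were quantile normalization, centring of each array on its median, no filter and a 60th percentile filter, eBayes without a trend and with a robust trend, the replicate number as a block, an unmoderated linear model, a minimum of 2-fold, a threshold of 0.1, the estimated correlation, the mean of a gene's probe sets, shared genes left out, and each array left out in turn. A restriction to probe sets above the background bound on an array of each group was added after the data were seen. Intervals of list medians are 95% bootstrap intervals over genes from 10000 draws, and describe genes, not pools.

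The procedure was tested on simulated data. With 200 changed probe sets among 10335 in the comparison of transgenic and wild type, 16% of those shifted by 1 on the log2 scale were recovered, 88% of those shifted by 2, 98% at 4 and 100% at 8, and 9 of the 160 calls were false. With no change added, 0 lists were called over 6479 genes. With the cell cycle list shifted by 1, that list was called and 0 others. The simulated genes varied independently, with equal spread in both groups. These runs therefore do not check the list calls where genes of a list correlate. The 200 simulated changes are also far fewer than the 2250 probe sets called in the data. The recovery rates and the share of false calls therefore hold for the simulated setting only. The work used R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.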

Results

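The upper digestive tract of adult zebrafish was profiled in 3 pools of zCdx1b transgenic fish and 2 pools of wild-type fish. Each pool held tissue of 3 fish aged 3 months on the AB background, and the sex of the fish and the ends of the dissected stretch are not given in the sources used here. Per the labels, the transgene carried zebrafish Cdx1b and EGFP behind a fragment of the zebrafish keratin 5 promoter and was inserted by the Tol2 transposon system. Cdx1b is a homeobox transcription factor of the caudal family, whose members act in the intestinal epithelium, and keratin 5 belongs to stratified epithelium. Over all probe sets, the transgenic arrays correlated with each other across genes at r = 0.912 to 0.983 and the wild-type arrays at r = 0.941. Between the groups r ran from 0.726 to 0.822, and the first principal component, with 76.6% of the variance, separated transgenic from wild-type pools. Genes are not independent replicates, so these correlations describe the arrays only.

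The question of the design was how the zCdx1b transgene altered expression in this tissue. No probe set was named cdx1b in the tables used here, so the level of the transgene's own coding sequence was not analysed here. The related gene cdx4 rose by 2.31 (log2, SE 0.31, limma adjusted p = 0.00487), from 3.03 ± 0.27 (SD, n = 2) in wild-type pools to 5.34 ± 0.47 (SD, n = 3) in transgenic pools, at least 2.73-fold. Another caudal gene, cdx1a, at or below the background bound in both wild-type pools, was at least 1.38-fold higher in the transgenic pools without passing the test, with a limma adjusted p of 0.0613. That gene passed after quantile normalization, with an adjusted p of 0.0315, and without wild-type pool 2, with an adjusted p of 0.0444. The array's EGFP control probe set read 4.56, 4.14 and 4.23 in the transgenic pools and 4.15 and 4.62 in the wild-type pools, which overlap. The control probe sets for pAsRed2 and pDsRed1 read at a similar level, with means of 4.11 and 4.15 in transgenic and 4.14 and 4.32 in wild-type pools. Which part of EGFP the EGFP probe set covers is not given in the sources used here, so its level does not check the labels.

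The largest rises in transgenic pools included prss1, ctrb.1, cela1.6 and ela3l of the exocrine pancreas list and apoa1a, chia.1, fabp1b.1 and chia.3 of the intestinal absorptive list. The largest falls included pkp1b, anxa1c and col17a1b of the squamous epithelium list and myl13 of the striated muscle list. Leaving out genes known only by a clone or locus name, the 12 genes with the largest fitted rise were apoa1a, prss1, ctrb.1, apoea, chia.1, fabp1b.1, chia.3, the gene with the symbol cell, lgals2b, cela1.6, ela3l and chia.2, with log2 changes from 9.97 to 8.89. Apolipoprotein gene apoa1a went from 3.23 ± 0.29 (SD, n = 2) in wild-type pools to 13.20 ± 0.05 (SD, n = 3) in transgenic pools, at least 636-fold. The trypsin gene prss1 was at least 646-fold higher, and the fatty acid binding protein gene fabp1b.1 at least 306-fold higher. Their wild-type values lay at or below the background bound in both wild-type pools for 11 of these 12 genes, the exception being the elastase gene cela1.6, at 4.17 ± 0.35 (SD, n = 2). For these 11 the changes are therefore lower bounds, from at least 306-fold to at least 646-fold, so their order is not fixed, and apoa2, with a change of 8.67, exceeds some of these bounds. With the same genes left out, the 12 genes with the largest fall were saa, pkp1b, dnase1l4.1, anxa1c, capn9, abca12, selenow2b, col17a1b, tcnbb, myl13, scinla and dbnla, with log2 changes from -3.93 to -3.32. The acute phase gene saa, for example, was 10.24 ± 0.40 (SD, n = 2) in wild-type and 6.32 ± 1.71 (SD, n = 3) in transgenic pools.

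In all, 2250 of the 10335 probe sets kept passed limma's test with Benjamini-Hochberg adjustment, of which 1043 were higher and 1207 lower in transgenic pools. Which direction had more calls depended on the arrays and settings, with 633 higher and 346 lower without transgenic pool 2, 1221 and 869 without wild-type pool 1, 914 and 1700 without wild-type pool 2, 1115 and 1564 after quantile normalization and 935 and 780 at a minimum of 2-fold. Large changes were mostly rises: 185 probe sets rose by over 16-fold and 2 fell by as much. Of the higher probe sets, 291 had both wild-type arrays at or below the background bound, and of the lower ones 82 had all 3 transgenic arrays there. The groups did not overlap for 5261 probe sets, 50.9% of those kept, against 20% by chance with 3 and 2 arrays. By gene, 728 rose and 729 fell among 6479. The 12 largest rises had limma adjusted p-values from 1.2e-05 to 1.7e-05 and passed with each pool left out in turn. The 12 largest falls had adjusted p-values from 0.00235 to 0.0419, and 10 of them did not pass without wild-type pool 1 and 9 without wild-type pool 2, with adjusted p of up to 0.156 for anxa1c. With a robust trend saa and anxa1c did not pass, at 0.0603 and 0.0767. Without transgenic pool 2 the count of changed probe sets was 979.

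**Figure D1:**
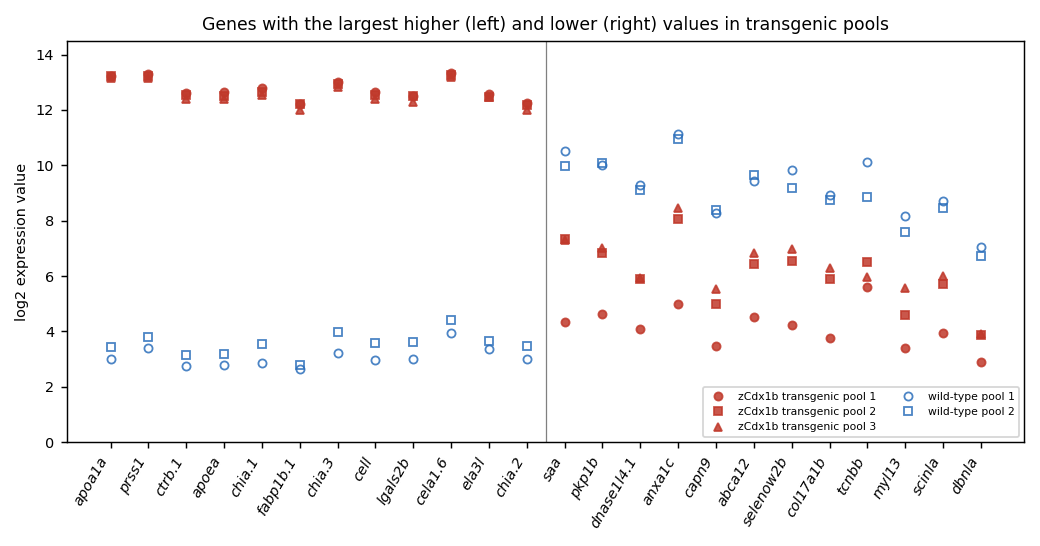
Log2 expression value (vertical axis) of the 12 genes with the largest rise and the 12 with the largest fall, leaving out genes known only by a clone or locus name (horizontal axis), with 1 point per pool: red filled symbols for the 3 zCdx1b transgenic pools and blue open symbols for the 2 wild-type pools. The rising genes went from values near background to about the top of the array, while the falling genes started from higher wild-type values and varied more between transgenic pools, as with saa, at 6.32 ± 1.71 (SD, n = 3).

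Genes of the absorptive intestinal epithelium rose as a group. Of 58 measured intestinal absorptive markers, 44 rose, 5 fell and 9 did not pass, with a median log2 change of 4.30. The chitinase genes chia.1 and chia.3 rose by 9.47 and 9.31, at least 439-fold and 525-fold. Among further members, chosen after their values were seen, the brush border gene vil1 rose by 5.48 and the fatty acid binding protein gene fabp2 by 5.96. The 5 that fell, also singled out afterwards, were vill (-2.32), foxa2 (-1.93), alpi.1 (-1.41), scinlb (-1.36) and foxa1 (-0.78). The list was higher than other genes by limma's camera test (Benjamini-Hochberg adjusted p = 6.5e-25), with adjusted p = 0.468 with an estimated correlation. Against no change, which is what fry tests here and for the other lists, p was 0.000101. With the 26 members at or below background in a group set at their bound, the median was 4.01. Exocrine pancreas and hepatocyte markers moved with this group in the same pools, at medians of 7.25 and 3.76.

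Some goblet and mucus secretory genes fell. Of 23 goblet and mucus secretory genes, 1 rose, 8 fell and 14 did not pass, with a median log2 change of -0.45. The membrane mucin gene muc13b rose by 6.19, at least 58.4-fold, while the calpain gene capn9 fell by 3.66, the claudin gene cldn3c by 2.22 and the forkhead factor gene foxa2 by 1.93. The mucin genes muc5.1 and muc5.2, chosen after their values were seen, had changes of -3.03 and -3.24 without passing. camera put the list lower than other genes (adjusted p = 0.0263), with adjusted p = 0.661 with an estimated correlation, and fry, against no change, gave p = 0.0679. The camera call was lost without wild-type pool 1, at a median of -0.29 and adjusted p = 0.0937 (-0.74 without wild-type pool 2), and with genes shared between lists left out, at -0.38 and adjusted p = 0.133. The call of capn9 was lost without wild-type pools 1 and 2, at adjusted p = 0.0574 and 0.0545, and that of cldn3c without these, at 0.156 and 0.0946, and without transgenic pool 2, at 0.0677. Squamous epithelium markers, which share agr1 with this list, fell in the same pools with a median of -2.05.

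Exocrine pancreas genes had the highest list median. Of 25 exocrine pancreas markers, 24 rose, 0 fell and 1 did not pass, with a median log2 change of 7.25, or 7.11 with 14 members at their bound. The chymotrypsinogen gene ctrb.1 and the elastase gene ela3l rose by at least 8.63 and 8.62 on the log2 scale, and the other named members were prss1 and cela1.6. The insulin gene ins, on the same list and chosen after its value was seen, rose by 5.35, and the member that did not pass was nr5a2, at 0.85. camera gave adjusted p = 9.9e-31, with adjusted p = 0.468 with an estimated correlation, and fry gave p = 7.1e-05. The list median over the wild-type mean was 7.48, 7.28 and 7.11 in transgenic pools 1, 2 and 3.

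Hepatocyte genes rose in the same pools. Of 54 hepatocyte markers, 44 rose, 1 fell and 9 did not pass, with a median log2 change of 3.76, or 3.4 with 29 members at their bound and 1.85 over the 25 above background in both groups, a restriction chosen after the data were seen. The apolipoprotein gene apoea rose by 9.55, at least 396-fold, and apoa2 rose by 8.67. The protease inhibitor gene serpina1l rose by 8.38 and the haemopexin gene hpxa by 8.06, at least 266-fold and 202-fold. The member that fell was the sulfotransferase gene sult2st1 (-1.31), and the vitellogenin genes vtg2 and vtg4 had changes of -1.08 and -0.87 without passing, all 3 singled out after their values were seen. camera gave adjusted p = 1.3e-27, with adjusted p = 0.468 with an estimated correlation, and fry gave p = 0.000291.

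Hormone genes and sterol synthesis genes were also higher in transgenic pools. Of 14 enteroendocrine markers, which include islet hormones, 6 rose, 1 fell and 7 did not pass, with a median log2 change of 0.50. The somatostatin genes sst1.1 and sst2 rose by 5.29 and 5.23, the glucagon gene gcga by 4.17 and the enkephalin gene penkb by 2.79, and the first 3 of these were at least 24.1-fold, 25.7-fold and 11.2-fold higher. camera gave adjusted p = 0.00955 for this list, with adjusted p = 0.643 with an estimated correlation and a fry p of 0.00511. Its adjusted p was 0.0796 without wild-type pool 1. Among probe sets above background in both groups, a restriction chosen after the data were seen that drops the hormone genes at background in wild type, its median was -0.13 and its adjusted p 0.492. The median also moved with the filter, to 0.17 over 25 genes without a filter and 2.22 over 8 genes with the 60th percentile filter. Of 16 cholesterol synthesis genes, 10 rose, 1 fell and 5 did not pass, with a median of 1.59, or 1.55 with 2 members at their bound. The desaturase gene fads2 rose by 7.75, at least 158-fold, the regulator insig1 by 3.31, and the sterol enzyme genes msmo1 and dhcr7 by 2.91 and 2.48. camera gave adjusted p = 2.7e-06, with adjusted p = 0.612 with an estimated correlation, and fry gave p = 0.00179. Hepatocyte and exocrine pancreas markers rose in the same pools as both lists.

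Genes of stratified squamous epithelium fell. Of 62 squamous epithelium markers, 2 rose, 46 fell and 14 did not pass, with a median log2 change of -2.05. The desmosome gene pkp1b fell by 3.89, the annexin gene anxa1c by 3.86 and the hemidesmosome collagen gene col17a1b by 3.53. The keratin 5 gene krt5, whose promoter fragment drives the transgene, fell by 3.02 and the basal cell factor gene tp63 by 2.99, both chosen after their values were seen. The members that rose were anxa2b, by 3.65, and ponzr1, by 1.91, the latter singled out afterwards. camera gave adjusted p = 1.4e-15, with adjusted p = 0.643 with an estimated correlation, and fry gave p = 0.0145. The list median lay at -2.72, -1.67 and -1.56 relative to wild type in transgenic pools 1, 2 and 3. Without wild-type pool 1 the named falls had adjusted p-values of 0.0798 for pkp1b, 0.156 for anxa1c and 0.103 for col17a1b, and without wild-type pool 2 of 0.0719, 0.134 and 0.0828. Striated muscle markers fell in the same pools, with a median of -2.20.

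Striated muscle genes fell. Of 48 striated muscle markers, 0 rose, 15 fell and 33 did not pass. The myosin light chain gene myl13 fell by 3.39, the adenylate kinase gene ak1 by 3.01 and the Z-disc gene ldb3b by 2.98, and myl10 fell too. camera gave adjusted p = 1.6e-07, with adjusted p = 0.643 with an estimated correlation, and fry gave p = 0.0817. The list median differed between the pools, at -3.55 in transgenic pool 1, -1.81 in pool 2 and -1.09 in pool 3, and the list's median log2 change of -2.20 became -1.43 without transgenic pool 1. None of these 4 genes passed without wild-type pool 1, with adjusted p from 0.0845 for myl13 to 0.163 for ldb3b, or without wild-type pool 2, with 0.0542 for myl13 to 0.142 for ldb3b. Without transgenic pool 2 the adjusted p was 0.054 for myl10 and 0.0682 for ldb3b. With all 5 arrays ldb3b was lost without a filter, without a trend and with a robust trend, at 0.0512, 0.0536 and 0.0735, and ak1 with a robust trend, at 0.0611. Of 14 smooth muscle markers, 5 rose, 3 fell and 6 did not pass. The desmin gene desmb rose by 3.25, at least 7.39-fold, the smooth muscle actin gene acta2 by 2.32 and the transgelin gene tagln by 2.29, while the desmin gene of skeletal and heart muscle, desma, fell by 3.06. The call of desma was lost without wild-type pool 1, wild-type pool 2 and transgenic pool 2, at adjusted p = 0.136, 0.132 and 0.0527, and with a robust trend, at 0.0534. camera found no shift of the smooth muscle list (adjusted p = 0.958, estimated correlation adjusted p = 0.98, fry p = 0.378), and its median of -0.53 and mean of -0.11 had the opposite sign to the test's direction. That median was -0.18 without wild-type pool 1 and -0.83 without wild-type pool 2.

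Matrix genes were lower in transgenic pools. Of 37 fibroblast and extracellular matrix genes, 0 rose, 13 fell and 24 did not pass, with a median log2 change of -0.97. The homeobox gene prrx1a fell by 2.69, the lysyl oxidase gene loxa by 2.12, and the metalloproteinase gene mmp2 and the growth factor gene ccn2a had falls of -1.95 and -1.91. The collagen genes col1a2 and col1a1a, chosen after their values were seen, had changes of -2.67 and -2.23 without passing. camera gave adjusted p = 2.6e-05, with adjusted p = 0.643 with an estimated correlation, and fry gave p = 0.0285. Without wild-type pool 1 the adjusted p was 0.0677 for prrx1a, 0.0986 for mmp2 and 0.0831 for ccn2a, and the latter 2 were at 0.0614 and 0.0844 without wild-type pool 2 and at 0.0576 and 0.0575 without transgenic pool 2. Striated muscle markers fell beside this list, with a median of -2.20.

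Single hox genes fell, while the cdx and hox list did not pass. Of 9 cdx and hox genes, 1 rose and 4 fell, with hoxb5a at -2.40, hoxb3a at -1.87, hoxd4a at -0.73 and hoxb2a, singled out afterwards, at -0.57. The values of camera and fry for the list were a median of -0.57, adjusted p = 0.549, estimated correlation adjusted p = 0.803 and fry p = 0.0666. Among 6 genes above background in both groups, a restriction chosen after the data were seen that drops cdx4 by construction, it passed (median -0.68, adjusted p = 0.0215), and over 43 genes without a filter it had adjusted p = 0.728 and a median within 0.001 of 0. Without wild-type pool 1, hoxb5a had adjusted p = 0.196, hoxd4a 0.078 and hoxb3a 0.0583, and hoxd4a also failed after quantile normalization, with median centring and without a filter, at 0.0507, 0.0554 and 0.0634. hoxb5a failed without a filter, without a trend and with a robust trend, at 0.0548, 0.0534 and 0.0515. Without wild-type pool 2 and transgenic pool 2 the adjusted p of hoxb5a was 0.0731 and 0.0721 and that of hoxd4a 0.0557 and 0.167, and without transgenic pools 1 and 3 hoxd4a was at 0.0775 and 0.121. Of 41 hedgehog, wnt, bmp and notch pathway genes, 1 rose, 14 fell and 26 did not pass, with a median of -0.59, or -0.21 over 85 genes without a filter. The gut mesenchyme factor gene nkx2.3 rose by 2.34, while wnt11 fell by 2.36, the receptor gene notch2 by 1.86 and her9 by 1.79. camera gave adjusted p = 0.00236 for this list, with adjusted p = 0.643 with an estimated correlation and a fry p of 0.0206. Without wild-type pool 1 the adjusted p was 0.126 for wnt11, 0.108 for notch2 and 0.0812 for her9, whose change was then -1.16. Without transgenic pool 2 these were at 0.0664, 0.0779 and 0.0692, notch2 was at 0.0589 without wild-type pool 2, and her9 was at 0.0533 and 0.0604 without transgenic pools 1 and 3. Squamous epithelium and striated muscle markers, at medians of -2.05 and -2.20, fell beside both lists.

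Immune genes moved in both directions. Of 29 leukocyte markers, 2 rose, 9 fell and 18 did not pass, with a median log2 change of -0.73. The chemokine gene ccl25b fell by 2.40, the tetraspanin gene cd9b by 2.23 and the chemokine receptor gene cxcr4a by 2.07, while cpa5 rose by 7.23. That last gene, a carboxypeptidase, is also on the exocrine pancreas list. camera gave adjusted p = 0.0392, with adjusted p = 0.803 with an estimated correlation and a fry p of 0.182, and the call was lost without wild-type pool 1 (median -0.37, adjusted p = 0.2) and without wild-type pool 2 (median -1.16, adjusted p = 0.0547), and among genes above background in both groups, a restriction chosen after the data were seen (adjusted p = 0.0561). Of 21 inflammatory and acute phase genes, 2 rose, 2 fell and 17 did not pass. The complement genes c9 and c3a.1, which hepatocytes make and which stand on the hepatocyte list too, rose by at least 25.8-fold and 13.8-fold, while saa fell by 3.93 and mmp13a by 2.03. This list did not pass (median -0.66, adjusted p = 0.136, estimated correlation adjusted p = 0.803, fry p = 0.65), and passed with shared genes left out (median -0.69, adjusted p = 0.017), and above background (adjusted p = 0.0119), both of which drop c9 and c3a.1 by construction. Of 18 interferon response genes, ifi30a and isg15 rose by 1.75 and 1.17, irf1b fell, gbp1 fell by 1.07 and 14 did not pass (list median 0.28, camera adjusted p = 0.272, estimated correlation adjusted p = 0.894, fry p = 0.561). The interferon median was 0.58 without wild-type pool 1 and 0.02 without wild-type pool 2, and the inflammatory median was -0.39 without wild-type pool 1. Without wild-type pool 1 the adjusted p was 0.139 for saa, 0.0973 for ccl25b, 0.114 for cd9b and 0.0798 for mmp13a, and without wild-type pool 2 it was 0.0988 for saa, 0.058 for ccl25b, 0.0765 for cd9b and 0.0552 for isg15. Without transgenic pool 2 it was 0.154 for isg15, 0.0957 for irf1b, 0.0587 for gbp1 and 0.064 for mmp13a, without transgenic pool 3 it was 0.0547 for isg15 and 0.0626 for irf1b, and without transgenic pool 1 it was 0.0784 for isg15.

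Ribosomal protein genes fell by small amounts. Of 76 measured, 0 rose, 33 fell and 43 did not pass, with a median log2 change of -0.28 against -0.10 over all probe sets kept. The genes rpl23a, rpl29, rpl19 and rpl27 fell by 0.55, 0.52, 0.52 and 0.52. camera gave adjusted p = 9.4e-13, with adjusted p = 0.643 with an estimated correlation, and fry gave p = 0.00652. These 4 genes did not pass with eBayes run without a trend, with adjusted p from 0.0715 for rpl23a to 0.0894 for rpl29, and without transgenic pool 2 rpl29 and rpl27 were at 0.0724 and 0.0515. The gapdh control probe set at the 3' end read 8.08, 8.59 and 8.50 in the transgenic pools and 10.40 and 10.30 in the wild-type pools, and its difference from the 5' probe set was 0.63, 0.86 and 0.98 against 1.01 and 1.02.

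The other lists of general cell functions did not pass camera. Of 71 oxidative phosphorylation genes, 5 rose, 3 fell and 63 did not pass (median -0.01, mean 0.08, adjusted p = 0.634, estimated correlation adjusted p = 0.98, fry p = 0.855), with cox4i1l up by 2.36, ndufa4b by 1.94 and cox6b1 by 1.35 and cox8a down at -1.48. Of 47 immediate early and stress genes, 2 rose, 3 fell and 42 did not pass (median -0.24, adjusted p = 0.514, estimated correlation adjusted p = 0.894, fry p = 0.294), with dusp1 and sgk1 up by 1.68 and 1.66 and txnipa and ier5l down at -1.85 and -1.48. Of 24 circadian clock genes, cry2 fell by 1.29 and bhlhe40 by 0.85 (list median -0.28, adjusted p = 0.272, estimated correlation adjusted p = 0.867, fry p = 0.204), and the list passed without wild-type pool 1 (median -0.46, adjusted p = 0.000295) but not without wild-type pool 2 (median -0.09, adjusted p = 0.469). Of 15 erythrocyte markers, 1 fell, nt5c2l1 by 1.21 (list median 0.06, mean -0.06, adjusted p = 0.915, estimated correlation adjusted p = 0.98, fry p = 0.977). Of 72 cell cycle genes, 1 fell, mycn by 1.04 (list median 0.05, adjusted p = 0.549, estimated correlation adjusted p = 0.98, fry p = 0.9), and the list passed without transgenic pool 1 (median 0.26, adjusted p = 0.00445). The cell cycle median was -0.20 without transgenic pool 3 (camera adjusted p = 0.216). Without transgenic pool 2, dusp1, sgk1, cry2, bhlhe40, nt5c2l1, mycn, cox8a and cox6b1 did not pass, with adjusted p from 0.0527 for dusp1 to 0.182 for bhlhe40. Without transgenic pool 1 the adjusted p was 0.0945 for mycn, 0.0696 for nt5c2l1 and 0.0836 for bhlhe40, and without transgenic pool 3 it was 0.0826 for mycn and 0.0906 for bhlhe40. Without wild-type pool 1, mycn, which also failed without a filter (0.0614) and without a trend (0.0561), was at -0.63 with adjusted p = 0.0986 and nt5c2l1 at 0.0877, and without wild-type pool 2 nt5c2l1 was at 0.0679.

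Oocyte genes differed between pools of the transgenic group. Of 27 gonad markers, 0 rose, 1 fell and 26 did not pass, the fall being ybx1, by 1.05. The list median relative to wild type was -0.89 in transgenic pool 1, 1.29 in pool 2 and 2.83 in pool 3. The linker histone gene of oocytes, h1m, read 3.66, 7.19 and 9.11 in these pools and 5.97 and 5.84 in the wild-type pools, and the egg coat gene zp3b read 3.84, 7.19 and 8.60 against 5.62 and 5.23, both chosen after their values were seen. The list did not pass camera (median 0.81, adjusted p = 0.18, estimated correlation adjusted p = 0.9, fry p = 0.688), and passed without transgenic pool 1 (median 2.08, adjusted p = 2.6e-07), while without transgenic pool 3 its median was 0.09 (adjusted p = 0.938).

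**Figure D2:**
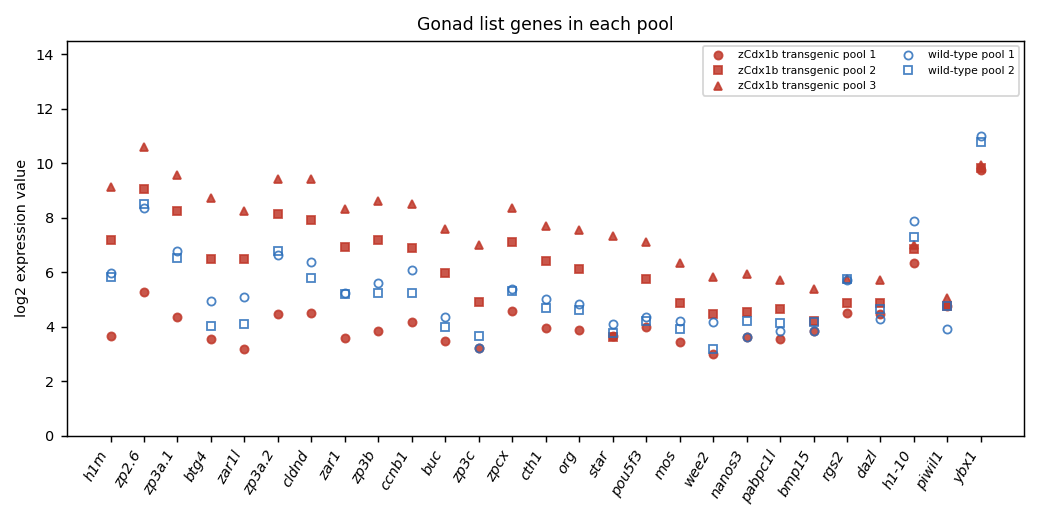
Log2 expression value (vertical axis) of the 27 gonad markers (horizontal axis), with 1 point per pool: red filled symbols for the 3 zCdx1b transgenic pools and blue open symbols for the 2 wild-type pools. For most genes the wild-type values lie between those of transgenic pools 1 and 3, as with h1m, at 5.97 and 5.84 between 3.66 and 9.11.

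Over the 22 lists, 12 passed camera, 5 higher and 7 lower. With an estimated correlation 0 passed, and the smallest unadjusted p-value was 0.0469, for intestinal absorptive markers, the only list under 0.05. By fry with Benjamini-Hochberg adjustment 7 lists passed, namely intestinal absorptive, exocrine pancreas, hepatocyte, enteroendocrine and squamous epithelium markers, cholesterol synthesis genes and ribosomal protein genes. Adjusted over the list alone, 45 intestinal absorptive markers rose and 6 fell, 25 exocrine pancreas markers and 47 hepatocyte markers rose, and 57 squamous epithelium markers, 23 striated muscle markers and 50 ribosomal protein genes fell. In the same terms 9 goblet and mucus secretory genes, 20 fibroblast and extracellular matrix genes, 17 pathway genes and 10 leukocyte markers fell, and 11 cholesterol synthesis genes and 6 enteroendocrine markers rose. Among the 6479 genes, 15 stood on more than 1 list.

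**Figure D3:**
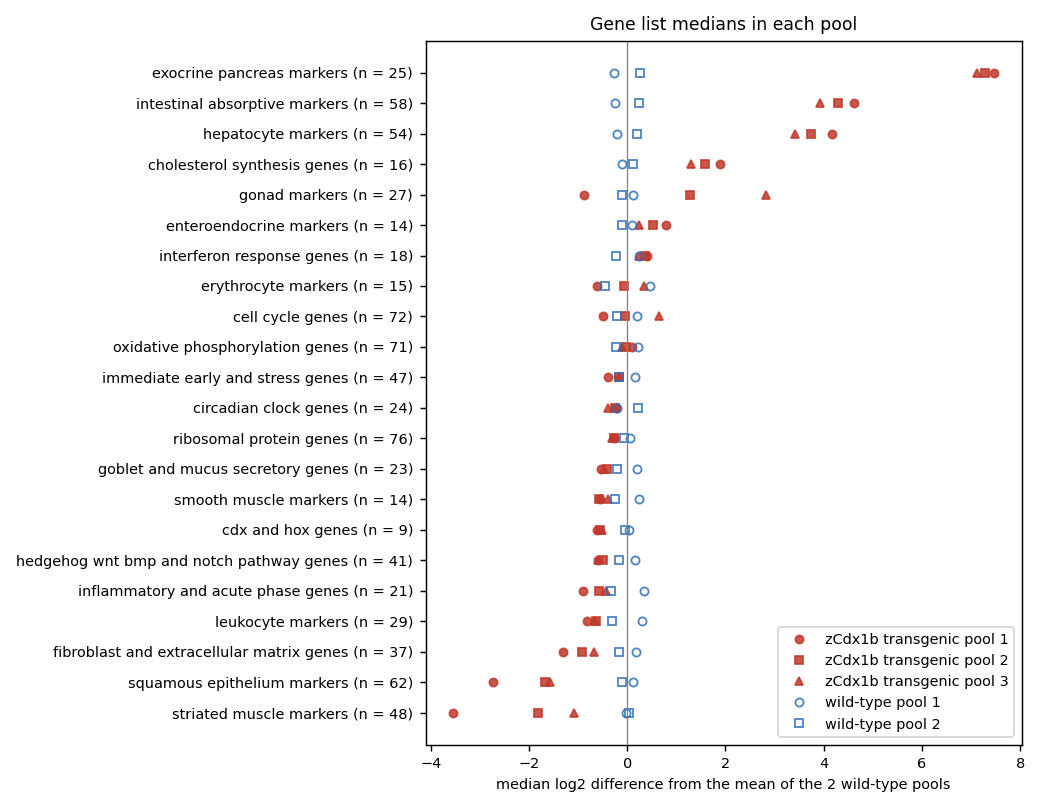
Median log2 difference from the mean of the 2 wild-type pools (horizontal axis) for each of the 22 gene lists (vertical axis, with the number of measured genes), with 1 point per pool: red filled symbols for zCdx1b transgenic pools and blue open symbols for wild-type pools. Exocrine pancreas markers lie between 7.11 and 7.48 in the 3 transgenic pools, gonad markers spread from -0.89 to 2.83, and striated muscle markers from -3.55 to -1.09.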

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

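Of the alternatives here, only the restriction to probe sets above background on an array of each group was chosen after the data were seen. The count of 2250 changed probe sets was between 1715 and 3153 in all alternatives with all 5 arrays except an unmoderated linear model, which gave 837, of which 757 were shared. Leaving out each array in turn gave 979 (without transgenic pool 2) to 2614 (without wild-type pool 2), with fewer arrays each time. The number of lists past camera was 12, 11 or 10 to 14 with each array left out, and 0 with an estimated correlation, where the medians of 4.30 for intestinal absorptive markers, -0.45 for goblet and mucus secretory genes and -2.05 for squamous epithelium markers did not change but the adjusted p rose to 0.468, 0.661 and 0.643. Other alternatives kept the intestinal and squamous calls, with medians of 3.17 to 4.68 and -2.32 to -1.60. The goblet call was lost with shared genes left out (-0.38) and without wild-type pool 1, and its medians ran from -0.74 to -0.29 with each array left out. The causes of these differences were not tested.

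Medians of lists that had not passed changed sign as follows: oxidative phosphorylation genes at 0.028 with median centring and -0.29 to 0.25 with each array left out, among them 0.06 without transgenic pool 3, cell cycle genes at -0.20 to 0.26 and erythrocyte markers at -0.65 to 0.64 with each array left out. Enteroendocrine markers changed to -0.13 above background, where hormone genes at background in wild type are dropped by construction. With the replicate number as a block, 1866 probe sets passed (1585 shared), and the oxidative phosphorylation, cell cycle and erythrocyte medians were 0.058, -0.20 and -0.46. Same-numbered arrays deviated from their group means with r = -0.254 and -0.125. The deviations of the 2 wild-type arrays mirror each other, so these values cannot show whether the numbers pair the pools. The labels tie no numbers to a shared day, so a pairing is neither given nor excluded. The leukocyte call was lost with the block (camera adjusted p = 0.0893). So were the limma calls of hoxd4a, irf1b, isg15, cry2 and bhlhe40, at adjusted p = 0.302, 0.126, 0.116, 0.0596 and 0.220. No named gene changed direction in any alternative: of 87, 58 to 82 kept their call under the block or with an array left out, and 80 to 86 under the other planned settings. Pseudocounts were not run, since the values were already log2, cdx1b gave no value, and eBayes settings do not enter the camera tests. Signal over background limits most of the largest folds, which are then lower bounds.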

Other observations

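The tests of explanations in this part were chosen after the results had been seen, while the comparison with wild type and the leaving out of single pools were planned.

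Spread between pools was uneven across genes. The standard deviation over the transgenic pools exceeded 1 (log2) for 373 probe sets, of which 46 passed the comparison with wild type, and that over the wild-type pools exceeded 1 for 323. The median standard deviation was 0.175 over transgenic and 0.315 over wild-type pools. The limma model took 1 spread for both groups, and the effect of unequal spread on its calls was not tested. The 74 probe sets that rose by over 64-fold had transgenic standard deviations of at most 0.32. Of the 10 ways to divide the 5 arrays into 3 and 2, 1 gave as many changed probe sets as the real division, namely the real one with 2250, and the highest of the others was 0. There are too few divisions for a share under 0.05. Each other division also mixes transgenic and wild-type arrays in a group, which adds the group difference to the spread. Its count is therefore no measure of chance.

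Exocrine pancreas and hepatocyte transcripts, whose lists share 1 of 25 and 3 of 54 genes with others, were higher in all 3 transgenic pools, with cela1.6 at 13.26 ± 0.08 and apoa2 at 12.61 ± 0.11 (SD, n = 3). After quantile normalization the exocrine pancreas median, without genes shared with other lists, was 7.44 (95% interval 6.15 to 8.40). All arrays already had the same mean, so that step could change the median only slightly and is a weak test of array scaling. A scale factor per array would shift all probe sets alike, whereas the median change over those kept was -0.10. Pancreas and liver tissue in the transgenic pools, nearly absent from the wild-type pools, as after dissection of different stretches, stays open as a hypothesis. Islet hormones rose with these lists. The smooth muscle median, predicted after the results were seen to rise too, was -0.53 (-1.13 to 1.35). It was -0.18 and -0.83 without wild-type pools 1 and 2. That list cannot decide the question, because its members went both ways. Among them desmb, acta2 and tagln rose, while desma, of skeletal and heart muscle, fell. A change of gut tissue brought about by the transgene was not tested and cannot be told apart from that hypothesis. This holds for the intestinal rise and for the rise of cdx4 too.

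Squamous epithelium transcripts fell in the transgenic pools. Loss of squamous gene expression alone, in tissue of the same makeup, predicts no fall of striated muscle markers, which belong to tissue outside the epithelium. Their median was -2.20 (95% interval over genes -2.44 to -1.47), and -1.43 without transgenic pool 1. It was negative in each transgenic pool, at -3.55, -1.81 and -1.09 in pools 1, 2 and 3. The interval covers genes and not pools, 33 of the 48 markers did not pass limma, and the list did not pass fry. These values lean against that explanation but do not exclude it. Dilution of squamous and muscle tissue by other tissue stays open as an account of part of the squamous fall. Averaged over the pools, the squamous median differed from the muscle median by 0.138 (-0.597 to 0.557). That interval includes 0 but does not show equal falls. By pool, the squamous medians without shared genes were -2.79, -1.68 and -1.56. Dilution by 1 factor per pool for both is argued against only by transgenic pools 3 and 1, compared after the values were seen. Between them the difference of squamous medians was lower than that of muscle medians, by -1.48 (-2.24 to -0.491). Each pool has 1 array, and the interval covers genes only. In transgenic pool 2 the squamous and muscle medians were close, at -1.68 and -1.81. An effect of the transgene on squamous epithelium, with or without dilution, was not tested and stays open.

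Oocyte transcripts were unequal between transgenic pools. The egg coat gene zp2.6, for example, read 5.29, 9.07 and 10.60 in the 3 pools. Between transgenic pools 3 and 1, the gonad median differed by more than the cell cycle median, by 2.63 (1.51 to 3.53). The cell cycle median moved in the same order, at -0.48, -0.04 and 0.64 in transgenic pools 1, 2 and 3. These 2 pools were chosen as the extremes of the gonad median, and the interval covers genes only. Unequal cell division in the dissected tissue therefore stays open. Ovary tissue carried into the pools in unequal amounts and the sex of the fish in each pool were not tested and stay open.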
